A study of Homo sapiens with 8 samples.

How the data were processed

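RNA of H1299 cells was measured on 8 one-colour microarrays of human microRNAs (miRNAs). The arrays fall into 4 groups of 2, named by what the cells overexpressed per the labels: EGFP, p53, ΔN-p53 and 14A. The label p53 is read here as full-length p53, which the labels do not state. The labels do not say what 14A is. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these arrays, which may be technical. All 8 arrays lie on 1 slide read in 1 scan, so slide and scan do not separate the groups.

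Per the labels, total RNA was extracted with Trizol, dephosphorylated and ligated to a Cy3-labelled nucleotide. Spot intensity was extracted with Agilent Feature Extraction 11.5.1.1, per the file headers, which subtracted a spatial background surface and marked outlier spots. The headers name human build hg19. The deposited intensity values were not scaled between arrays, and 49.1% of miRNA spots lay at or below 0. The deposited flags record spots well above background, saturated or outlying. The deposited series table holds log2 values. Each of its columns equalled the log2 of the scanner software's gene signal minus a constant per array, within 9.7e-06. The authors' choice of that constant is not given in the sources used here. Its column medians ran from -10.2 to -9.59. It was used only as an alternative, and 846 human names of its 939 names matched those of the array files. Names of miRNAs are those of the array design and can be old. The text leaves out the hsa- prefix and version suffixes.

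Each array has 15739 spots, of which 15024 are miRNA spots and 715 are controls. Control spots and outlier-marked spots were left out (6.27% of miRNA spots carried a mark). Saturated spots were kept, and only miR-494 and miR-923 had any. The processed signal was averaged over the spots of a probe and divided by the array's 75th percentile over the 299 human probes detected on all arrays. It was floored at the lowest scaled signal of a probe well above background on any array (log2 -5.01) and log2 transformed. A probe was detected on an array if at least 50% of its used spots were well above background. Over all arrays, 15.4% of measurements of the 2370 human probes were detected. Probes detected on both arrays of at least 1 group were tested, which left 373 probes of 202 among 851 human miRNAs. A miRNA's value was the mean over its tested probes. Of the 145 tested miRNAs with several tested probes, 18 to 64 had probes that differed in sign, depending on the comparison. Where a miRNA was above background on both arrays of a group and on neither of the other, the fold is a bound. The brighter group's mean was set against the higher, per array, of the dim probe's own signal and the lowest signal well above background. Such a bound holds for the settings first chosen and carries no error, so differences under other settings can fall below it.

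The number of arrays limits the precision. Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) over all 8 arrays, which gave 4 residual and 5.67 prior degrees of freedom. Two-sided p-values of each of the 6 comparisons were adjusted by the Benjamini-Hochberg method over the 202 miRNAs, at a threshold of 0.05. A moderated F test asked whether a miRNA differed among the 4 groups. Errors of log2 differences are standard errors (SE) of that fit. Files were read with data.table version 1.17.8 and figures drawn with matplotlib 3.10.9.

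In 20 simulations of p53 against EGFP over 202 miRNAs, 20 miRNAs were shifted by 1 and another 20 by 2 on the log2 scale. The test recovered 50.0% of the shifts of 1 and 93.5% of those of 2, with a mean of 1.3 false calls. A simulated shift of 1 over the let-7 family was recovered in 20 of 20 simulations. Noise was drawn separately for each miRNA, whereas let-7 members had an estimated correlation of 0.83 in the data. The recovery rates and false calls therefore do not show how the tests perform on miRNAs that move together.

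Of 21 lists fixed in advance, the 14 with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists of a comparison. The tested lists were p53-activated miRNAs, p53-targeting miRNAs, the miR-17/92a, miR-106b-25 and 14q32 clusters, the let-7, miR-29, miR-15/16, miR-30, miR-181, miR-221 and miR-23/miR-24/miR-27 groups, oncogenic and inflammatory miRNAs, and fragment-derived or array-prone entries. The last are array entries often traced to fragments of other RNAs or bright on many arrays. The other 7 were a list of the miR-200 family plus miR-205, and markers of blood, muscle, liver, neural, mesenchymal and pluripotent cells.

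The tests, the lists, the naming rule and the 22 alternative settings were chosen before the data were examined. The rule names the 12 largest rises and falls among miRNAs that passed the test with both arrays of a group beyond both of the other. In comparisons with 14A against p53 or ΔN-p53 it takes the 5 largest. Where fewer than 5 passed in a direction, as here throughout, it names the 5 with the smallest unadjusted p in that direction. It adds every tested member of the p53-activated and miR-17/92a lists, miR-186 and miR-210, but does not say for which comparisons. They are given for the comparisons against EGFP and for ΔN-p53 against p53, a choice made outside the rule, and the counts of named values depend on it. miR-186 was not detected on both arrays of any group and was not tested. Alternatives covered scaling (over all human probes, by the median, by quantiles or none), background (normexp with an offset of 50), the filter on dim probes, the probe summary, the floor, the deposited table, the replicate number as a block, the arrays in the fit, the variance model and each array left out. A correction for the GC content of probes and a covariate for the array-prone list were added after the data were seen.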

Results

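H1299, a human lung carcinoma line that lacks p53, was profiled for miRNAs after overexpression of full-length p53, of ΔN-p53, of something labelled only 14A or of the fluorescent control protein EGFP. ΔN-p53 is a p53 isoform without the amino-terminal end of the full-length protein. The series title speaks of miRNA signatures of the translation of protein isoforms, and the comparisons ask how miRNA levels differed from those with EGFP and among the other groups. Each group had 2 arrays. Of 851 human miRNAs on the array, 199 and 209 were detected on the ΔN-p53 arrays and 208 and 189 on the p53 arrays. EGFP arrays detected 186 and 184, and 14A arrays 187 and 216.

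Most markers of other cell types were not detected, on arrays where 15.4% of measurements of human probes were. No entry of the list of the miR-200 family, which marks epithelial cells, and miR-205 was detected on any array (0 of 6). No liver or mesenchymal marker was detected on any array either, nor were the 4 muscle markers. Of the blood markers, 6 of 7 were detected on no array and none was tested. The neural marker miR-128 and the pluripotent marker miR-371-5p were detected on all arrays, each the only tested member of its list. Of 52 array entries of the imprinted 14q32 cluster, 46 were detected on no array.

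Replicates differed in tightness. The replicate SD on the log2 scale was 0.19 for 14A, 0.24 for p53, 0.44 for ΔN-p53 and 0.52 for EGFP (n = 2 each). Between the EGFP arrays, members of the let-7, miR-17/92a and miR-15/16 lists were lower in replicate 2 by a median log2 difference of -0.95, with 0 of 19 higher. Array-prone entries differed the other way, by 0.53, with 28 of 32 higher. The plot of list levels by array shows these lists on opposite sides of their means on most arrays. Scaling and background moved the median log2 difference of all miRNAs: against EGFP it was 0.11 for ΔN-p53, 0.04 for p53 and -0.14 for 14A. It was 0.19, 0.31 and -0.01 with scaling over all human probes, -0.11, -0.29 and -0.0046 unscaled, and 0.12, 0.45 and -0.13 with the normexp background.

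**Figure D1:**
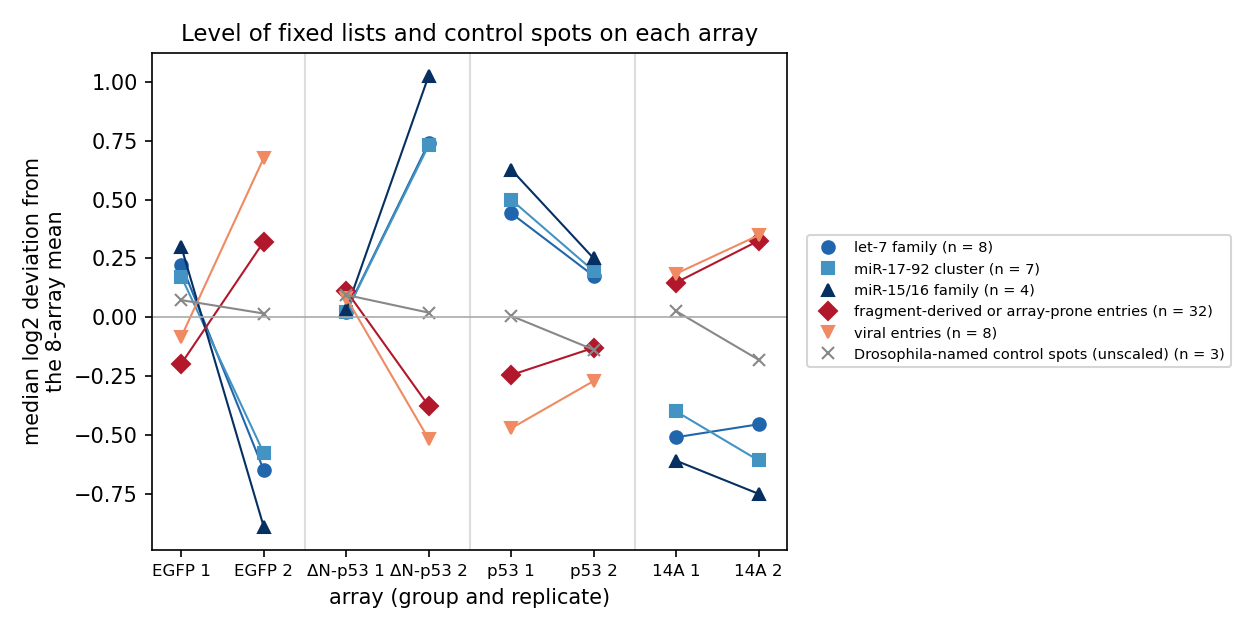
Median log2 deviation of each list from its mean over the 8 arrays (vertical axis), for each array by group and replicate (horizontal axis). Points are medians over the members given in the legend and lines join the replicates of a group. The let-7 family lay at -0.65 and array-prone entries at 0.32 on EGFP replicate 2, against 0.74 and -0.38 on ΔN-p53 replicate 2.

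Full-length p53 was compared with EGFP to find its miRNA response. miR-34a, a direct transcriptional target of p53 that represses cell cycle genes, had the smallest p of all miRNAs. Its log2 level was -2.96 ± 0.17 in p53 cells and -4.69 ± 0.45 in EGFP cells (SD, n = 2 each). Both p53 arrays were above both EGFP arrays, and the fitted log2 difference was 1.74 ± 0.34 (SE). It was 0.97 with the normexp background, 2.87 with the scanner software's gene signal and 5.08 with the values of the deposited table, and passed with none of these. Both p53 arrays detected miR-34a and neither EGFP array did, so with the settings first chosen the bound was at least 2.31-fold. This bound carries no error, and the normexp difference lies below it. Over all miRNAs miR-34a did not pass (limma, adjusted p = 0.0944). When adjusted over the list alone it passed (adjusted p = 0.00299), as 1 of 6 tested p53-activated miRNAs. Its log2 difference was 2.07 without EGFP replicate 1 and 1.41 without EGFP replicate 2, each with 1 EGFP array left. Such fits measure no spread between EGFP arrays. The difference was 1.39 without ΔN-p53 replicate 1 and 1.74 without ΔN-p53 replicate 2. The main fit used the longer of 2 miR-34a probes. On the shorter, unscaled signals were 18.5 and 16.1 on p53 arrays and 11.9 and 6.92 on EGFP arrays. Without ΔN-p53 replicate 1 the shorter probe passed the filter and was averaged in. With no filter on dim probes, which keeps both, the difference was also 1.39. With all arrays kept, miR-34a passed with scaling over all human probes (0.0299). In fits chosen after the data were seen, it passed with GC correction (0.0308) and the array-prone covariate (9.7e-06). It also passed when only these groups were fitted (0.00438). With no replicate left out, the adjusted p ranged from 9.7e-06, with the array-prone covariate, to 1. The tested probe, ACAACCAGCTAAGACACTGC, and a shorter one map to chromosome 1, 9211751 to 9211769 (hg19), in the miR-34a gene.

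The other tested p53-activated miRNAs were also above EGFP without passing. Of the 19 on the list, 13 were detected on no array and say nothing about a rise. miR-34a and miR-34b* were detected on neither EGFP array and entered the test only through other groups, which favours a value above EGFP. miR-34b*, from a paralogous locus, differed by log2 0.67 ± 0.36 and was detected on both p53 arrays and on neither EGFP array (at least 1.08-fold). miR-16 differed by 1.05 ± 0.52, miR-15a by 0.96 ± 0.48, miR-107 by 0.50 ± 0.35 and miR-22 by 0.21 ± 0.28. Without scaling miR-22 was below EGFP, at -0.12. Each of these miRNAs was lower on EGFP replicate 2 than on EGFP replicate 1, as miR-16 at -1.13 against 0.58. The list's median was 0.81, against 0.04 for all miRNAs. Camera with a preset correlation placed the list above the other miRNAs (adjusted p = 0.00605), but this was lost at adjusted p = 0.759 with an estimated correlation. Its level followed the array pattern described above, with -0.84 on EGFP replicate 2 and 0.16 on EGFP replicate 1.

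**Figure D2:**
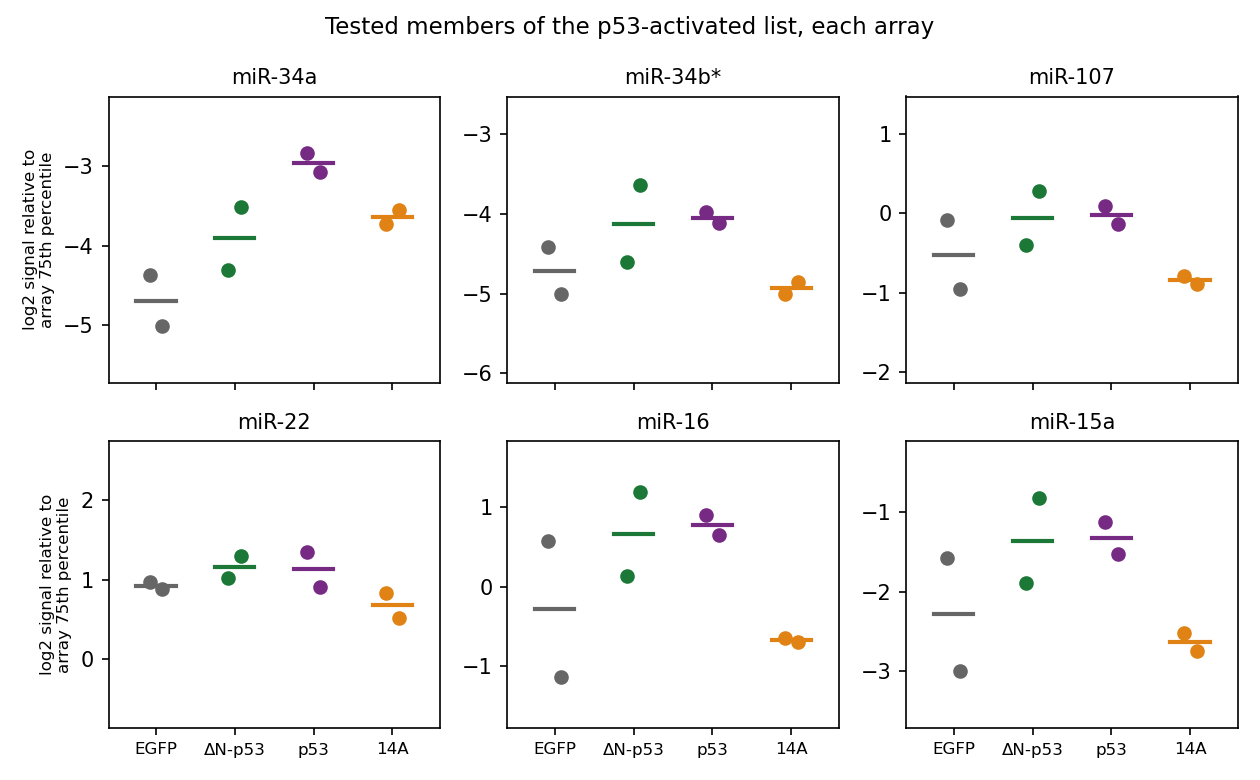
Log2 signal relative to the array's 75th percentile (vertical axis) of the 6 tested p53-activated miRNAs, by group (horizontal axis). Points are single arrays and bars are means of 2 arrays, and each panel spans the same log2 range. miR-34a was highest in the p53 group, at a mean of -2.96, and lowest in the EGFP group, at -4.69.

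Members of the oncogenic miR-17/92a cluster were mixed between p53 and EGFP. miR-18a (1.5 ± 0.51), miR-19a (1.28 ± 0.53), miR-20a (1.0 ± 0.43), miR-19b (0.56 ± 0.35) and miR-17 (0.34 ± 0.32) were above EGFP on the log2 scale. miR-17* (-0.10 ± 0.30) and miR-92a (-0.03 ± 0.25) were close to 0, and both turned positive with scaling over all human probes (0.17 and 0.24) and with the normexp background (0.44 and 0.10). None passed, and neither did the list (camera, adjusted p = 0.0660). miR-7 (1.26 ± 0.53) and miR-301b (0.87 ± 0.36, at least 1.13-fold) were among the 5 smallest p on the higher side. miR-18a was detected on 1 EGFP array and 1 14A array, and miR-7 on 1 EGFP array. Their differences from those groups, here and below, are therefore not exact. The same limit applies to other miRNAs detected on 1 array of a group. On the lower side stood miR-1826 (-1.51 ± 0.32, adjusted p = 0.0944), miR-431* (-1.03 ± 0.26, at least 1.37-fold lower), miR-1246 (-1.12 ± 0.31), miR-665 (-1.09 ± 0.31, at least 1.29-fold lower) and miR-345 (-1.24 ± 0.44). With the settings first chosen none of these passed over all miRNAs. miR-1826 passed when adjusted over the list alone, as 1 of 32 array-prone entries (limma, adjusted p = 0.0299). With all arrays kept, 7 named miRNAs, miR-34a included, passed with the array-prone covariate, chosen after the data were seen. The scanner software's gene signal and the deposited table each gave 1 named miRNA. A fit of only these groups gave 3, miR-34a included. miR-431* and miR-665 were higher in p53 cells with the normexp background, at 0.45 and 0.48. miR-1826 and miR-1246 belong to the array-prone list, whose median was -0.24 and which camera placed below the other miRNAs (adjusted p = 0.00145, lost at adjusted p = 0.759 with an estimated correlation). That median was 0.03 when arrays were scaled over all human probes, where the median of all miRNAs was 0.31. Hypoxia-induced miR-210 differed by -0.01 ± 0.24, or 0.26 with scaling over all human probes.

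The remaining lists did not pass between p53 and EGFP. Their median log2 differences were 0.47 for let-7, 0.74 for miR-15/16, 0.36 for miR-29, 0.29 for miR-23/miR-24/miR-27, 0.29 for oncogenic and inflammatory miRNAs, 0.07 for miR-106b-25, 0.05 for miR-30, 0.04 for the miR-221 group and 0.01 for p53-targeting miRNAs. The median was -0.13 for miR-181 and -0.28 for the 14q32 cluster. All of these except let-7, miR-15/16 and miR-29 changed sign under at least 1 scaling or, for the 14q32 cluster, with the normexp background (0.38). The means of p53-targeting miRNAs (-0.05) and of the miR-221 group (-0.02), and camera's directions for both, were opposite in sign to their medians. In the 14q32 cluster miR-431* passed when adjusted over the list alone (adjusted p = 0.01), and the other 3 tested members are also array-prone entries. By limma, 0 of 202 miRNAs passed, and 17 had an unadjusted p under 0.05, 6 of them higher and 11 lower. Both p53 arrays lay beyond both EGFP arrays for 40.6% of miRNAs, against 33.3% by chance. That 33.3% is the expectation for a single miRNA. The miRNAs moved together, with 82.5% of the variance on 1 axis, so shares far from 33.3% can arise by chance. These shares were not tested in any comparison. Leaving out EGFP replicate 1 gave 54 calls, leaving out ΔN-p53 replicate 1 gave 2 and leaving out ΔN-p53 replicate 2 gave 1. The 2 lists that passed became 6 without EGFP replicate 1, 0 without EGFP replicate 2, 4 without ΔN-p53 replicate 2 and 5 without 14A replicate 1. With all arrays they became 1 with GC correction and 0 with the array-prone covariate.

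For ΔN-p53 against EGFP, miR-34a lay between the p53 and EGFP levels. Its log2 difference from EGFP was 0.79 ± 0.34 (adjusted p = 0.554 by limma). It was detected on 1 of the 2 ΔN-p53 arrays and on neither EGFP array, so this difference is not exact and has no bound. The difference was 0.40 without ΔN-p53 replicate 2, 0.44 without EGFP replicate 2 and 0.29 with the normexp background. It was 1.60 with the scanner software's gene signal and 3.85 with the deposited table. All 6 tested p53-activated miRNAs were above EGFP, with a median of 0.69 against 0.11 for all miRNAs. miR-16 differed by 0.94 ± 0.52, miR-15a by 0.93 ± 0.48, miR-107 by 0.46 ± 0.35 and miR-22 by 0.23 ± 0.28. miR-34b* differed by 0.59 ± 0.36, which is not exact, as it was detected on 1 ΔN-p53 array and on neither EGFP array. With the settings first chosen none passed over all miRNAs or when adjusted over the list alone. Without EGFP replicate 1, which left 1 EGFP array, the log2 difference of miR-34a was 1.11.

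The miR-17/92a cluster was also above EGFP in ΔN-p53 cells, with a median of 0.58. miR-18a differed by 1.35 ± 0.51, miR-19a by 1.21 ± 0.53, miR-20a by 1.01 ± 0.43, miR-19b by 0.58 ± 0.35 and miR-17 by 0.43 ± 0.32. miR-17* (0.13 ± 0.30) and miR-92a (0.02 ± 0.25) were close to 0 and were negative without scaling (-0.09 and -0.19). The tumour-suppressive let-7 family had a median of 0.61, with let-7a at 0.95 ± 0.41. miR-29b-1* (0.85 ± 0.31) was also among the smallest p. Lower were miR-1826 (-1.03 ± 0.32), miR-198 (-1.14 ± 0.39), miR-1182 (-0.92 ± 0.36), miR-574-5p (-0.79 ± 0.29) and miR-431* (-0.76 ± 0.26). miR-210 differed by -0.08 ± 0.24, or 0.00046 with scaling over all human probes. With the settings first chosen none of these passed (limma, adjusted p = 0.554 at the smallest). With the array-prone covariate, chosen after the data were seen, 9 named miRNAs passed with all arrays kept.

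By limma 0 of 202 miRNAs passed between ΔN-p53 and EGFP, and 13 had an unadjusted p under 0.05 (6 higher, 7 lower). Groups were fully apart for 19.8% of miRNAs, against 33.3% by chance. Camera with a preset correlation placed p53-activated (adjusted p = 0.0336), miR-17/92a (0.0336), let-7 (0.0266) and miR-15/16 miRNAs (0.0497) above the others and array-prone entries below (0.00158). All 5 were lost at adjusted p = 0.678 with an estimated correlation. Without EGFP replicate 1 there were 49 calls. The 5 lists became 0 without ΔN-p53 replicate 2, 0 without EGFP replicate 2 and 2 without 14A replicate 2. GC correction and the array-prone covariate each left 0 lists with all arrays.

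In 14A cells miR-34a again had the smallest p against EGFP. Its log2 difference was 1.06 ± 0.34, and both 14A arrays and neither EGFP array detected it. With the settings first chosen the bound on this difference was at least 1.44-fold. This difference was 0.15 with the normexp background and 0.72 without EGFP replicate 2, where the p of miR-34a ranked 111 and 57 among all miRNAs. It was 2.32 with the scanner software's gene signal and 4.62 with the values of the deposited table. miR-34a passed neither over all miRNAs (limma, adjusted p = 0.928) nor when adjusted over the list alone (adjusted p = 0.0674). With the array-prone covariate, chosen after the data were seen, it passed (1.28 ± 0.18, adjusted p = 2.26e-05), in a range over 23 alternatives of 2.26e-05 to 1. Of the other 5 tested p53-activated miRNAs, those detected were below EGFP: miR-16 (-0.39 ± 0.52), miR-15a (-0.35 ± 0.48), miR-107 (-0.32 ± 0.35) and miR-22 (-0.25 ± 0.28), none of which passed. miR-34b* was detected on no array of either group, so neither the sign of its difference nor its reversals under alternatives carry information. With EGFP replicate 1 left out, miR-16 (0.49), miR-15a (0.38) and miR-107 (0.14) were above EGFP, and with the array-prone covariate miR-16 (0.06) and miR-15a (0.07) were too. The list's median was -0.28 and its mean -0.08, while camera's direction was up (adjusted p = 0.784).

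With all arrays, the 7 tested miR-17/92a members were below EGFP in 14A cells without passing: miR-19a (-0.40 ± 0.53), miR-17 (-0.32 ± 0.32), miR-19b (-0.29 ± 0.35), miR-20a (-0.28 ± 0.43), miR-17* (-0.26 ± 0.30), miR-18a (-0.22 ± 0.51) and miR-92a (-0.13 ± 0.25). miR-92a was positive with scaling over all human probes (0.0020) and without scaling (0.0084). When EGFP replicate 1 was left out, miR-18a (0.63), miR-19a (0.40), miR-20a (0.36), miR-19b (0.10) and miR-17 (0.01) were above EGFP, so this direction rests on that array. The array-prone covariate also made miR-18a (0.20), miR-19a (0.08) and miR-20a (0.08) positive. miR-210 differed by -0.45 ± 0.24. Higher in 14A cells were miR-601 (0.68 ± 0.35), miR-517* (0.68 ± 0.27), miR-502-3p (0.60 ± 0.29) and miR-500a* (0.52 ± 0.27). Lower were miR-1260 (-0.83 ± 0.34), miR-1826 (-0.66 ± 0.32), miR-431* (-0.59 ± 0.26), miR-149 (-0.55 ± 0.27) and miR-615-3p (-0.51 ± 0.25). By limma 0 of 202 passed, and 4 had an unadjusted p under 0.05 (2 higher, 2 lower). Groups were fully apart for 25.2% of miRNAs, against 33.3% by chance. Camera placed only the array-prone entries apart, above the others (median 0.07, adjusted p = 0.0194, lost at adjusted p = 0.833 with an estimated correlation). Without EGFP replicate 2 there were 2 calls and 3 lists, and without 14A replicate 1 there were 0 lists. With all arrays, GC correction and the array-prone covariate each gave 0 lists.

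The isoforms were also set against each other. miR-34a was lower in ΔN-p53 than in p53 cells by log2 -0.95 ± 0.34 and had the smallest unadjusted p, 0.0193, without passing (limma, adjusted p = 1.0). Without ΔN-p53 replicate 1, where the shorter miR-34a probe was averaged in, the difference was -0.45. With the array-prone covariate, chosen after the data were seen, it passed (-0.88 ± 0.17, adjusted p = 0.00407), in a range over 23 alternatives of 0.00407 to 1. The other p53-activated miRNAs were close to 0: miR-16 (-0.11 ± 0.52), miR-34b* (-0.08 ± 0.36), miR-107 (-0.03 ± 0.35), miR-15a (-0.03 ± 0.48) and miR-22 (0.02 ± 0.28). So were the miR-17/92a members, with miR-17* at 0.23 ± 0.30, miR-17 at 0.09 ± 0.32, miR-92a at 0.05 ± 0.25, miR-19b at 0.02 ± 0.35, miR-20a at 0.0045 ± 0.43, miR-19a at -0.07 ± 0.53 and miR-18a at -0.14 ± 0.51. All of these except miR-34a changed sign under at least 1 alternative. miR-210 differed by -0.07 ± 0.24, or 0.04 without scaling.

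On the higher side in ΔN-p53 cells stood miR-1246 (0.56 ± 0.31), miR-1260 (0.55 ± 0.34), miR-1826 (0.48 ± 0.32), miR-517* (0.38 ± 0.27) and miR-665. miR-665 was detected on 1 ΔN-p53 array and on no p53 array, so its difference is not exact. With the normexp background miR-517* (-0.30) and miR-665 (-0.54) were lower. Lower were miR-105 (-0.46 ± 0.26), miR-191* (-0.45 ± 0.40, or 0.20 without ΔN-p53 replicate 2 and 0.12 without p53 replicate 1), miR-574-5p (-0.43 ± 0.29) and miR-542-5p (-0.39 ± 0.36). By limma 0 of 202 passed between the isoforms and 1 had an unadjusted p under 0.05. Groups were fully apart for 9.41% of miRNAs, against 33.3% by chance. Camera placed 0 lists apart, with the p53-activated list nearest (median -0.05, or 0.06 without scaling, adjusted p = 0.0735). The miR-17/92a list had a median of 0.02 while camera's direction was down. Lists that passed numbered 2 without either ΔN-p53 replicate or without p53 replicate 2, and 1 without either EGFP replicate.

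14A and p53 cells were fully apart for more miRNAs than any other pair of groups. Lower in 14A cells were the miR-17/92a members miR-18a (-1.72 ± 0.51), miR-19a (-1.68 ± 0.53) and miR-20a (-1.28 ± 0.43), with miR-720 (-0.89 ± 0.30). miR-191* was also among the 5 smallest p on the lower side, but lay at the floor on both 14A arrays, so its difference is not exact. Higher were miR-149* (1.27 ± 0.38, at least 1.49-fold), miR-1471 (1.1 ± 0.37), miR-1246 (0.83 ± 0.31), miR-193b* (0.78 ± 0.29) and miR-502-3p (0.78 ± 0.29). With the normexp background miR-149* (-0.51), miR-193b* (-0.20) and miR-502-3p (-0.29) were lower. None passed over all miRNAs (limma, adjusted p = 0.199 at the smallest). When adjusted over the list alone, 3 miR-17/92a and 3 miR-15/16 members passed. Of the 10 named, 7 passed over all miRNAs without EGFP replicate 1 and 8 without EGFP replicate 2. Groups were fully apart for 80.7% of miRNAs, against 33.3% expected for a single miRNA, a difference that was not tested.

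By limma 0 of 202 passed between 14A and p53, and 46 had an unadjusted p under 0.05 (15 higher, 31 lower in 14A). Camera placed p53-activated (median -0.85, adjusted p = 0.0393), let-7 (-0.72, 0.0393), oncogenic and inflammatory (-0.56, 0.0393) and miR-17/92a miRNAs (-0.85, 0.0430) below the others and array-prone entries above (0.41, 1.06e-05). All were lost at adjusted p = 0.641 with an estimated correlation. The median of all miRNAs was -0.22, or 0.25 unscaled and -0.57 with the normexp background. A fit of only these groups called 106 miRNAs, leaving out EGFP replicate 1 gave 41, and leaving out EGFP replicate 2 gave 40. The normexp background gave 94 calls, of which 90 were lower in 14A, and unscaled arrays gave 30, of which 30 were higher. The 5 lists became 1 without p53 replicate 2 and 3 without 14A replicate 2. With all arrays they became 1 with the normexp background, 1 with no filter on dim probes, and 0 with GC correction or the array-prone covariate.

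Against ΔN-p53, the lower miRNAs in 14A cells with the smallest p were miR-19a (-1.61 ± 0.53), miR-18a (-1.58 ± 0.51), let-7a (-1.31 ± 0.41), miR-20a (-1.28 ± 0.43) and miR-15b (-1.18 ± 0.39). Higher were miR-198 (1.18 ± 0.39), miR-1471 (0.93 ± 0.37), miR-1182 (0.89 ± 0.36), miR-193b* (0.82 ± 0.29) and miR-765 (0.74 ± 0.30). None passed over all miRNAs (limma, adjusted p = 0.201 at the smallest). When adjusted over the list alone, 3 miR-17/92a and 4 miR-15/16 members passed. Of the 10 named, 9 passed over all miRNAs without ΔN-p53 replicate 1, and as many without either EGFP replicate. Groups were fully apart for 71.3% of miRNAs, against 33.3% expected for a single miRNA, a difference that was not tested.

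By limma 0 of 202 passed between 14A and ΔN-p53, and 49 had an unadjusted p under 0.05 (7 higher, 42 lower in 14A). Camera placed let-7 (median -0.82), miR-17/92a (-0.87) and oncogenic and inflammatory miRNAs (-0.65) below the others (adjusted p = 0.0368 each) and array-prone entries above (0.33, adjusted p = 2.54e-05). All were lost at adjusted p = 0.539 with an estimated correlation. The median of all miRNAs was -0.27, or 0.08 unscaled. Calls numbered 37 without ΔN-p53 replicate 1, 47 without EGFP replicate 1, 35 without EGFP replicate 2 and 21 when only these groups were fitted. The 4 lists became 1 without ΔN-p53 replicate 2, and 0 with GC correction or the array-prone covariate.

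Over the 4 groups together, miR-34a had the smallest adjusted p of limma's F test, 0.381. By that test 0 of 202 miRNAs passed, and 18 had an unadjusted p under 0.05. There were 55 calls without EGFP replicate 1 and 26 without EGFP replicate 2. No list passed fry in any of the 6 comparisons.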

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

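The correction for probe GC content and the covariate for the array-prone list were tests chosen only after the result was seen.

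Each named miRNA was recomputed under every alternative that could give it a value. With all arrays kept, 1556 of 1701 values kept their direction and did not pass, 58 passed in the same direction and 87 reversed. The replicate block, the trended variance and the fit of only the compared groups cannot reverse a difference (0 of 108 each). None of these numbers includes miRNAs that lost their probes, as miR-34a did when probes had to be detected on all arrays. With 1 array left out, 743 of 864 kept direction and did not pass, 74 passed and 47 reversed. A lone array was then assumed to vary like those of other groups, so passes that involve its group carry no measure of that group's own spread. Leaving out an EGFP array also removed the widest replicate spread (SD 0.52) from the shared error. The higher miR-34a in p53 than EGFP cells kept its direction in 23 of 23 alternatives (log2 0.97 to 5.08). The brightest probe, the replicate block, the trended variance and the fit of only these groups returned the same 1.74. They could not change the direction, so the count overstates how often it was tested. The 5.08, from the deposited table, had an SE of 1.91. With no replicate left out, the adjusted p by limma ran from 9.7e-06 to 1. With limma, the lower floor, the replicate number as a block and the trended, robust variance gave 0 calls in every comparison, as did the settings first chosen, where 1 to 49 miRNAs had an unadjusted p under 0.05. Deviations by replicate number correlated positively among p53, 14A and EGFP (0.41 to 0.70) and negatively between ΔN-p53 and each of them (-0.90 to -0.33). With 2 arrays per group and 1 dominant axis, these values cannot tell whether replicate numbers pair the arrays.

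Counts of miRNAs and of lists past the threshold (camera, preset correlation) changed with several settings, and the cause was not tested. With no filter on dim probes, list calls numbered 9 for ΔN-p53 against EGFP, 8 for p53 against EGFP, 8 for ΔN-p53 against p53, 1 for 14A against p53 and 10 for 14A against ΔN-p53. With only probes detected on all arrays, list calls numbered 3 for ΔN-p53 against EGFP and 3 for 14A against p53. With the scanner software's gene signal, miRNA calls numbered 1 for p53 against EGFP. List calls numbered 3 for ΔN-p53 against EGFP, 5 for p53 against EGFP, 0 for 14A against EGFP and 2 for 14A against ΔN-p53. With the deposited table, miRNA calls numbered 1 for ΔN-p53 against EGFP, 1 for p53 against EGFP, 2 for ΔN-p53 against p53, 1 for 14A against p53, 1 for 14A against ΔN-p53 and 2 for the F test. List calls numbered 2 for ΔN-p53 against EGFP, 4 for p53 against EGFP and 2 for 14A against ΔN-p53. With GC correction, miRNA calls numbered 1 for p53 against EGFP. List calls numbered 0 for ΔN-p53 against EGFP, 1 for p53 against EGFP, 0 for 14A against EGFP, 0 for 14A against p53 and 0 for 14A against ΔN-p53. With array-prone covariate, miRNA calls numbered 12 (6 higher, 6 lower) for ΔN-p53 against EGFP, 11 (3 higher, 8 lower) for p53 against EGFP, 2 for 14A against EGFP, 1 for ΔN-p53 against p53, 2 for 14A against p53 and 11 for the F test. List calls numbered 0 for ΔN-p53 against EGFP, 0 for p53 against EGFP, 0 for 14A against EGFP, 0 for 14A against p53 and 0 for 14A against ΔN-p53. With 75th percentile over all human probes, miRNA calls numbered 1 for p53 against EGFP. With no scaling between arrays, miRNA calls numbered 30 (30 higher, 0 lower) for 14A against p53. List calls numbered 4 for p53 against EGFP. With normexp background, offset 50, miRNA calls numbered 94 (4 higher, 90 lower) for 14A against p53, 7 (0 higher, 7 lower) for 14A against ΔN-p53 and 25 for the F test. List calls numbered 1 for p53 against EGFP, 2 for ΔN-p53 against p53 and 1 for 14A against p53. With brightest probe, list calls numbered 4 for p53 against EGFP. With only the 2 groups compared, miRNA calls numbered 3 (2 higher, 1 lower) for p53 against EGFP, 106 (34 higher, 72 lower) for 14A against p53 and 21 (1 higher, 20 lower) for 14A against ΔN-p53. List calls numbered 1 for ΔN-p53 against p53. With median over probes detected on all arrays, list calls numbered 1 for ΔN-p53 against p53. The fit of only the compared groups has fewer arrays. The median number of detected miRNAs per array was 194, and 169.5 when all used spots had to be well above background.

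Over the 8 fits that each leave out 1 array, calls ran from 0 to 49 for ΔN-p53 against EGFP, 0 to 54 for p53 against EGFP, 0 to 2 for 14A against EGFP, 0 to 41 for 14A against p53, 0 to 47 for 14A against ΔN-p53 and 0 to 55 for the F test. They were 0 throughout for ΔN-p53 against p53. Without EGFP replicate 1 they were 49, 54, 0, 41, 47 and 55 in that order. Without EGFP replicate 2 they were 2 for 14A against EGFP, 40 for 14A against p53, 35 for 14A against ΔN-p53 and 26 for the F test. Without ΔN-p53 replicate 1 they were 2 for p53 against EGFP and 37 for 14A against ΔN-p53, and without ΔN-p53 replicate 2 they were 1 for p53 against EGFP. List calls ran from 0 to 6 for ΔN-p53 against EGFP, 0 to 6 for p53 against EGFP, 0 to 3 for 14A against EGFP, 0 to 2 for ΔN-p53 against p53, 1 to 7 for 14A against p53 and 1 to 6 for 14A against ΔN-p53.

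Named log2 differences that reversed are given by setting, and the cause was not tested. With normexp background, offset 50, p53 against EGFP gave miR-431* 0.45, miR-665 0.48, miR-17* 0.44, miR-210 0.25 and miR-92a 0.10, ΔN-p53 against p53 gave miR-517* -0.30, miR-665 -0.54, miR-17 -0.13, miR-17* -0.30, miR-20a -0.069 and miR-92a -0.044, 14A against p53 gave miR-149* -0.51, miR-193b* -0.20 and miR-502-3p -0.29, ΔN-p53 against EGFP gave miR-210 0.00021. With no scaling between arrays, ΔN-p53 against EGFP gave miR-17* -0.088 and miR-92a -0.19, p53 against EGFP gave miR-22 -0.12, 14A against EGFP gave miR-92a 0.0084, ΔN-p53 against p53 gave miR-107 0.079, miR-15a 0.082, miR-16 0.00050, miR-19a 0.044, miR-210 0.040 and miR-34b* 0.038. With GC correction, ΔN-p53 against EGFP gave miR-17* -0.038, p53 against EGFP gave miR-210 0.046 and miR-92a 0.075, ΔN-p53 against p53 gave miR-19b -0.026, miR-20a -0.039 and miR-22 -0.021. With array-prone covariate, ΔN-p53 against EGFP gave miR-17* -0.0072 and miR-92a -0.027, 14A against EGFP gave miR-15a 0.073, miR-16 0.063, miR-18a 0.20, miR-19a 0.077, miR-20a 0.078 and miR-34b* 0.022, ΔN-p53 against p53 gave miR-107 0.048, miR-15a 0.10, miR-16 0.031, miR-19a 0.080 and miR-34b* 0.0013. With 75th percentile over all human probes, ΔN-p53 against EGFP gave miR-210 0.00046, p53 against EGFP gave miR-17* 0.17, miR-210 0.26 and miR-92a 0.24, 14A against EGFP gave miR-92a 0.0020, ΔN-p53 against p53 gave miR-17 -0.097, miR-19b -0.17, miR-20a -0.18, miR-22 -0.16 and miR-92a -0.14. With median over probes detected on all arrays, ΔN-p53 against EGFP gave miR-92a -0.084, ΔN-p53 against p53 gave miR-19b -0.033, miR-20a -0.047, miR-22 -0.029 and miR-92a -0.0013. With quantile normalization, ΔN-p53 against EGFP gave miR-92a -0.020, ΔN-p53 against p53 gave miR-17 -0.0034, miR-19b -0.042, miR-20a -0.032, miR-22 -0.078 and miR-92a -0.0023. With brightest probe, p53 against EGFP gave miR-210 0.037 and miR-92a 0.15, 14A against EGFP gave miR-92a 0.066, ΔN-p53 against p53 gave miR-17 -0.16, miR-19b -0.037, miR-20a -0.046 and miR-22 -0.12. With the scanner software's gene signal, p53 against EGFP gave miR-92a 0.037, 14A against EGFP gave miR-18a 0.42 and miR-92a 0.046, ΔN-p53 against p53 gave miR-17 -0.079, miR-19b -0.069, miR-20a -0.064 and miR-22 -0.10. With the deposited table, 14A against EGFP gave miR-18a 2.72 and miR-92a 0.078, ΔN-p53 against p53 gave miR-17 -0.047, miR-19b -0.036, miR-20a -0.032 and miR-22 -0.069. With no filter on dim probes, ΔN-p53 against p53 gave miR-18a 0.032 and miR-34b* 0.015.

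Log2 differences that reversed when 1 array was left out had these ranges over the 8 fits. ΔN-p53 against p53 ranged as follows: miR-191* -0.85 to 0.20, miR-107 -0.37 to 0.31, miR-15a -0.56 to 0.50, miR-16 -0.64 to 0.42, miR-17 -0.23 to 0.42, miR-17* -0.10 to 0.56, miR-18a -0.60 to 0.56, miR-19a -0.65 to 0.52, miR-19b -0.34 to 0.38, miR-20a -0.45 to 0.46, miR-210 -0.13 to 0.0051, miR-22 -0.19 to 0.25, miR-34b* -0.55 to 0.44 and miR-92a -0.074 to 0.19. ΔN-p53 against EGFP ranged as follows: miR-17* -0.19 to 0.46, miR-210 -0.16 to 0.0016 and miR-92a -0.090 to 0.13. p53 against EGFP ranged as follows: miR-17* -0.22 to 0.045, miR-210 -0.073 to 0.084, miR-22 -0.013 to 0.43 and miR-92a -0.16 to 0.11. 14A against EGFP ranged as follows: miR-107 -0.77 to 0.14, miR-15a -1.08 to 0.38, miR-16 -1.27 to 0.49, miR-17 -0.66 to 0.013, miR-18a -1.07 to 0.63, miR-19a -1.19 to 0.40, miR-19b -0.68 to 0.095, miR-20a -0.91 to 0.36 and miR-34b* -0.54 to 0.080.

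Signal over background limited what was tested: 15.4% of measurements of human probes were detected, and a miRNA below background in every group has no value here.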

Other observations

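The GC, stringency, labelled-RNA and dim-probe tests below, and the GC correction and array-prone covariate, were chosen only after the result was seen.

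Detection differed between groups for a few miRNAs. miR-1281, miR-182, miR-197 and miR-221* were detected on both ΔN-p53 arrays and on neither EGFP array. In p53 cells miR-301b, miR-34a and miR-34b* were so, and in 14A cells miR-1281, miR-34a and miR-602. miR-431* and miR-665 were detected on both EGFP arrays and on neither p53 array. Of 88 viral miRNAs on the array, which uninfected cells lack, 8 were tested, and the smallest adjusted p by limma against EGFP was 0.26, for ebv-miR-BART19-3p in p53 cells (log2 -1.03).

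One axis across arrays, computed from the human miRNAs alone, held 82.5% of the variance. Levels of let-7, miR-17/92a and miR-15/16 miRNAs ran against those of array-prone entries. Viral entries, which were not part of the axis, varied with the array-prone entries. The axis also parted the EGFP replicates (scores 2.53 and -7.39) and the ΔN-p53 replicates (-0.44 and 7.97). The explanations below were examined only between the EGFP arrays. Probe GC content argued for only part of it: the EGFP difference correlated with GC across 202 miRNAs (Spearman's rho 0.65; miRNAs are not independent replicates), yet removing the GC trend left the EGFP replicate SD at 0.40, from 0.52, against 0.19 in 14A. Higher stringency on EGFP replicate 2 predicted that the shortest probe of a miRNA lost more than its longest in most miRNAs. The share was 37.2% of 145 (exact 95% interval 29.4% to 45.7%), against that prediction. The interval treats miRNAs as independent, although they moved together and come from 1 pair of arrays. It is therefore too narrow, and the test does not settle stringency. A lower share of cellular miRNA in the labelled RNA is a candidate explanation. Viral entries were higher in EGFP replicate 2 in 8 of 8 cases (median log2 0.68), but that rise belongs to the pattern to be explained. The 14A arrays lie at the same end of the axis, so a 14A effect stays open and untested.

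The higher miR-34a in p53 cells was weighed against this axis and against noise. With the array-prone covariate its log2 difference from EGFP was 1.41 ± 0.19 (SE), so a linear adjustment left a difference. The covariate came from the same arrays. miR-34a was above background on neither EGFP array and lay at the floor (log2 -5.01) on EGFP replicate 2. The fit therefore cannot tell how much of the difference the axis accounts for. Of 50 other miRNAs among the dimmest, 0.0% differed as much, but this decides nothing, because the fitted difference of miR-34a that it used was the largest of all 202 and was taken against a signal not above background in EGFP cells. Noise of dim probes therefore stays open, beside induction by p53, which may be the source. With no replicate left out, the adjusted p of miR-34a by limma ran from 9.7e-06 to 1.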
